A study of Homo sapiens with 2 samples.

How the data were processed

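RNA was extracted from KASUMI-1 cells and 1 sequencing library was made per group, from the cells infected with the pccl or the USP6 lentivirus, per the labels' protocols. The submitters' processing notes name HISAT2 2.0.4, StringTie 1.3.3b and edgeR, without the role of each. The genome build, the annotation, the strandedness of the libraries and the selection of RNA before library preparation were not given in the sources used here. The labels assign each library to its group, and the columns of the deposited table carry the same names.

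The deposited table lists 50868 genes by Ensembl identifier and symbol, with a locus, a read count and an FPKM value per library. The counts deposited by the authors are whole numbers that sum to 12306442 in the pccl library and 12518795 in the USP6 library. The FPKM values deposited by the authors equal the count divided by a gene length and by the total count of the column. In all 16030 genes with a count in both libraries, the implied gene length was the same in both within 0.1%. FPKM is thus scaled by a total that includes the mitochondrial genome, and a gene's FPKM ratio equals its ratio of count shares. Of the 50111 identifiers found in GENCODE release 29, 94.9% had the identical locus, and coordinates are given as the file lists them. Gene types and the GC content of the longest transcript were taken from that release, and 45 expressed genes had no GC value.

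Values of genes with 1 symbol were summed, which left 50464 symbols. A gene was taken as expressed with at least 1 FPKM in the higher library. The size of a difference was log2((USP6 + 1)/(pccl + 1)) of the FPKM values, with a pseudocount of 1, and genes at or past 1 or -1 were counted as higher or lower. With 1 library per group there are 0 residual degrees of freedom, so no test was made, although the table holds counts. Folds are ratios of FPKM without a pseudocount, with an exact conditional binomial (Clopper-Pearson) interval at 95% from the counts. A count of 0 was to be set to a floor of 3 counts for a fold, and no fold is printed where both libraries were at or under it.

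The 42 gene lists, the named genes and the settings above were fixed before the data were examined. Named genes were USP6, USP32, RUNX1, RUNX1T1 and detected TBC1D3 genes, then the 12 highest and the 12 lowest genes with at least 5 FPKM in the higher library, leaving out pseudogenes and symbols that are only identifiers. From each list described, up to 4 expressed members with the largest absolute log2 ratio could be named, and any member at or past 1 or -1. Some genes that this rule names are not reported here. Each list was summarised by the members at or past a log2 ratio of 0.58 (1.5-fold) on the scale with the pseudocount. Genes can pass 1.5-fold in FPKM without reaching that limit. The percentile of the list's median was taken among 10000 random lists of the same size, matched on mean expression in 20 classes. Lists with under 5 expressed members got no percentile. The percentile limits of 2.5 and 97.5 were set after the list medians, and before any percentile, had been seen.

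The counts of genes were repeated with pseudocounts of 0.1, 0.5 and 5, a filter of 5 FPKM or none, values scaled to the same FPKM sum, to a median log2 ratio of 0, to the upper quartile or by the trimmed mean of M values (edgeR 4.0.16), a 1.5-fold limit, each gene identifier on its own, and protein-coding genes alone. Scaling to the same FPKM sum raised the values of both libraries, which weakens the pseudocount and the filter. Lists were repeated with some of these settings, with unmatched random lists and without the member of largest ratio. Chosen after the data were seen were centring on a lowess trend with GC content (span 0.3), random lists matched on 8 classes of expression and 5 of GC, depth from nuclear genes alone, and lists with 1 FPKM asked of the mean of both libraries or with all members that have a count in either. The bootstrap intervals of rho used 1000 draws of genes.

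The steps were tested on simulated data for the USP6 library against the pccl library, with Poisson counts for 50464 genes. All 100 genes set to a 4-fold difference and all 100 set to 8-fold were recovered (100% each). These genes were drawn from those with a mean FPKM high enough for such folds to pass the limit, so their recovery does not cover genes near 1 FPKM. Of 9214 expressed genes with no set difference, 0.185% were counted. Among 200 random lists of 20 genes with no shift, 4% lay beyond the percentile limits, against 100% of 50 lists shifted by 0.5. Poisson counts hold no variation between cultures, so these shares are not error rates for the real libraries. R 4.3.3, Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.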

Results

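Gene expression was measured by RNA sequencing in KASUMI-1, a human acute myeloid leukaemia cell line that carries the RUNX1-RUNX1T1 fusion. The cells had been infected with a lentivirus labelled pccl, taken here as the control, or with one labelled USP6, after the ubiquitin-specific protease of that name. The series title names the stabilisation of RUNX1 fusion proteins by this deubiquitinase, and the comparison asks how the messages of the USP6 library differed from those of the pccl library. Each group held 1 library, so no difference below has a replicate check and no test was run. The libraries had similar depth, with 12306442 counts in the pccl library and 12518795 in the USP6 library, over 17880 and 18140 genes with a count. The mitochondrial genome took 49.9% of the counts of the pccl library (95% Clopper-Pearson interval 49.8 to 49.9) and 45.6% of those of the USP6 library (45.6 to 45.7). All intervals cover counting error only and no differences between cultures or preparations, since each group is 1 library. They may be too narrow even for counting error, since reads copied from 1 molecule by PCR are not independent.

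USP6 itself was low in both libraries and higher in the USP6 library. It had 8 counts (0.0396 FPKM, fragments scaled by gene length and library total) in the pccl library and 70 counts (0.340 FPKM) in the USP6 library, an 8.60-fold difference with a 95% counting interval of 4.13 to 20.7. Both levels lay under the 1 FPKM taken as expression. These counts are those of the annotated gene, and whether reads of the lentiviral construct were assigned to it is not known, so the level of the introduced message remains open. USP6 (ENSG00000129204) is listed on chromosome 17 from 5116438 to 5175034. Its parent gene USP32, from which most of its protease sequence derives, went the other way, with 2.65 FPKM in the pccl library and 1.08 in the USP6 library (2.45-fold lower, 2.02 to 2.99). Of the TBC1D3 family, the other parent, TBC1D3C had 0 and 2 counts, TBC1D3D 7 and 19, and TBC1D3L 24 and 29. These relatives share sequence with USP6 and their counts are uncertain. Summed over USP6, USP32 and the TBC1D3 genes, counts were 393 in the pccl library and 267 in the USP6 library. That is a ratio of 0.668 (0.570 to 0.782), opposite in direction to USP6 alone. USP32 had most of these counts, 354 and 147, so the sum follows USP32 and does not test the difference seen for USP6.

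RUNX1 and RUNX1T1 were both lower in the USP6 library. RUNX1 (ENSG00000159216, chromosome 21 from 34787801 to 36004667) had 8.15 FPKM in the pccl library and 4.83 in the USP6 library, 1.69-fold lower (1.57 to 1.81). RUNX1T1 (ENSG00000079102, chromosome 8 from 91954967 to 92103286) had 3.30 and 2.63 FPKM, 1.26-fold lower (1.16 to 1.36). The fusion message carries parts of both genes, and counts per gene do not separate it from the normal messages. Centred on the trend with GC content described below, the log2 ratio was -0.52 for RUNX1 and 0.02 for RUNX1T1.

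Across the transcriptome, genes stood apart in both directions. Of 10153 genes with at least 1 FPKM in 1 of the libraries, 1396 were higher and 1156 lower in the USP6 library by at least 1 on the scale of log2((USP6 + 1)/(pccl + 1)), on which low genes show smaller differences than their fold. The median over these genes was 0.06. Scaled to the same, larger FPKM sum, which weakens the pseudocount and the filter, 11529 genes passed. Of these, 2199 were higher and 1172 lower, so that 65.2% of the counted genes were higher, against 54.7% as deposited. With the trimmed mean the lower genes were the more numerous, 1314 against 1159 higher (46.9%), as they were with a median log2 ratio of 0 (1280 against 1212, 48.6%) and with depth from nuclear genes (1337 against 1128, 45.8%). The highest were led by the linker histone gene H1-2, and the lowest by HGF, which encodes hepatocyte growth factor, and GFI1, a transcriptional repressor needed for granulocyte development. The counting interval of the ratio excluded 1 for 1377 of the higher and 1143 of the lower genes. These genes were picked by the size of that ratio in the same libraries, so this lends them no further support.

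H1-2 (ENSG00000187837, chromosome 6 from 26055787 to 26056428) had 1.77 FPKM in the pccl library and 59.3 in the USP6 library, 33.5-fold higher (19.8 to 61.7). IER5L was 11.1-fold higher (9.84 to 12.7), the tropomyosin gene TPM2 10.7-fold (9.55 to 12.1) and QPRT, an enzyme of NAD synthesis, 10.1-fold (8.84 to 11.6). PRAM1, an adaptor protein of myeloid cells, had 13.1 and 92.9 FPKM, 7.08-fold higher (6.57 to 7.63), and INKA1 had 21.2 and 146 FPKM. ABHD10, NUPR1 and the interleukin-10 receptor gene IL10RB were 14.5-fold, 55.1-fold and 21.6-fold higher. BASP1 rested on 1 count in the pccl library against 436 in the USP6 library, a ratio of 429 with a counting interval of 76.5 to 16967. C19orf54 and CORO6, 28.8-fold and 28.3-fold higher, overlap other expressed genes, ITPKC and SNRPA for the former and ANKRD13B for the latter, and reads could have been split among them.

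HGF (ENSG00000019991, chromosome 7 from 81699006 to 81770438) had 50.2 FPKM in the pccl library and 2.21 in the USP6 library, 22.8-fold lower (20.3 to 25.5). GFI1 (ENSG00000162676, chromosome 1 from 92474762 to 92486876) had 894 and 4 counts, 227-fold lower (88.5 to 836). Both ubiquitin-conjugating enzymes among the lowest, UBE2K and UBE2E1, were 21.3-fold (18.7 to 24.4) and 19.2-fold lower (15.1 to 24.8). The lactate transporter SLC16A1, which overlaps its antisense gene SLC16A1-AS1, was 41.5-fold lower, and the zinc transporter SLC39A8 51.3-fold lower. The sterol synthesis gene HMGCS1 was 52.6-fold (35.2 to 82.5), the ceramide synthase gene CERS6 36.3-fold (28.5 to 46.7) and HACD2 48.5-fold lower (30.1 to 83.6). ZNF146 had 1266 and 7 counts. DDI2 had 2139 counts in the pccl library and 2 in the USP6 library, a ratio of 1088 with a counting interval of 301 to 8989. RCC1 was 31.9-fold lower and overlaps SNHG3 and SNORA73B.

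**Figure D1:**
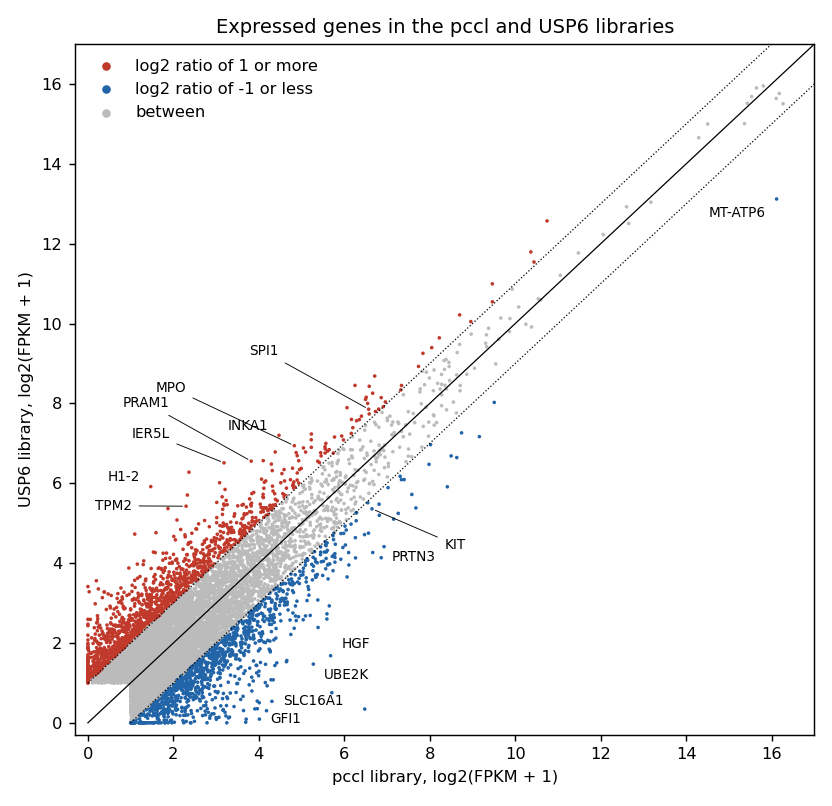
Expression of each expressed gene in the pccl library (x axis) and the USP6 library (y axis), both as log2(FPKM + 1), with 1 point per gene and 1 library per axis. The solid line marks equality and the dotted lines a log2 ratio of 1 and -1, with 1396 genes (red) at or above and 1156 genes (blue) at or below them, H1-2 and HGF among the farthest.

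The ratios followed the GC content of the transcripts, with GC-rich genes higher in the USP6 library. Over 8255 protein-coding genes, Spearman's rho between log2 ratio and GC was 0.46 (bootstrap interval over genes 0.44 to 0.48), a relation across genes, which are not independent replicates. The median log2 ratio went from -0.48 in the lowest to 0.72 in the highest of 10 GC classes. After centring on this trend, 980 genes were higher and 996 lower among 10108 genes with a GC value. For each gene list below, 2 percentiles are therefore given, 1 among random lists matched on expression and 1 among random lists matched on expression and GC, both describing these libraries alone.

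**Figure D2:**
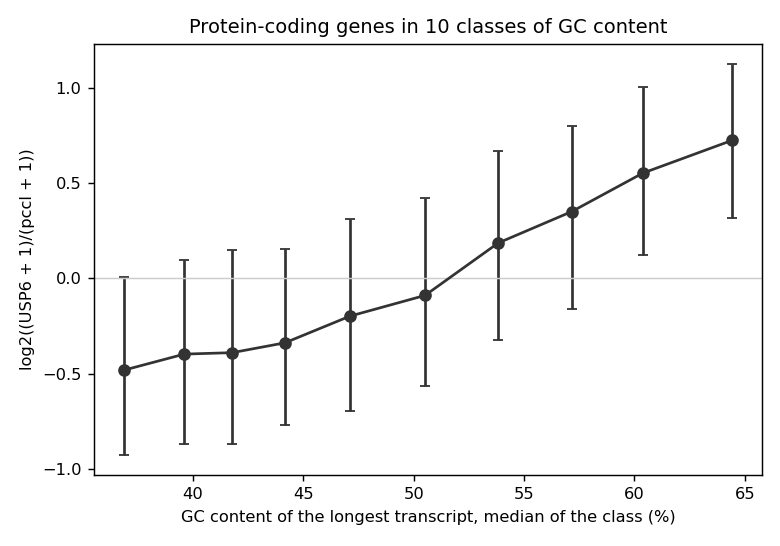
Median log2((USP6 + 1)/(pccl + 1)) of protein-coding genes (y axis) in 10 classes of equal size by the GC content of the longest transcript (x axis, median GC of the class in percent). Bars span the quartiles over genes, and the medians go from -0.48 in the lowest to 0.72 in the highest class.

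Genes of the core-binding factor complex and its partners were lower in the USP6 library, with exceptions. Of 12 expressed genes on this list, 7 were lower and 2 higher by at least 1.5-fold, and the median log2 ratio of -0.72 lay at percentile 0.85 with either matching. LDB1 was 7.48-fold lower (5.42 to 10.5), ERG 3.27-fold (2.88 to 3.73) and MYB 3.29-fold (2.86 to 3.81). LYL1 had 89.2 and 273 FPKM, 3.07-fold higher (2.96 to 3.17), and GATA2 was 2.44-fold higher (2.15 to 2.78). With a filter of 5 FPKM, which leaves fewer members, the median was still -0.72, at percentile 6.45, after centring on GC it was -0.52 at percentile 3.06, and with 1 FPKM asked of the mean of both libraries it was -0.65 at percentile 2.9.

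Genes reported elsewhere as raised by the RUNX1-RUNX1T1 fusion were mostly lower in the USP6 library. Of 11 expressed members, 6 were lower and 3 higher, with a median of -0.65 at percentiles 2.08 and 1.72. The median was -0.31 at percentile 6.08 with a pseudocount of 5, -0.57 at 3.93 without the member of largest ratio, -0.47 at 6.4 after GC centring and -0.06 at 19.9 over all 18 members with a count. The stem cell factor receptor gene KIT had 99.3 FPKM in the pccl library and 39.99 in the USP6 library, 2.48-fold lower (2.39 to 2.58), the progenitor marker CD34 was 3.01-fold lower (2.75 to 3.29) and the cyclin gene CCND2 3.42-fold lower (3.20 to 3.66). Genes reported as lowered by the fusion went both ways, with 8 higher and 4 lower of 18 and a median of 0.44 at percentiles 93.0 and 65.5. The myeloid transcription factors CEBPA and SPI1 were 3.91-fold (3.31 to 4.64) and 2.45-fold higher (2.37 to 2.54), and LGALS1 6.30-fold higher (5.04 to 7.94). After GC centring the log2 ratio of CEBPA was 0.99 and that of SPI1 0.52, against 1.79 and 1.29 before.

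Markers of maturing myeloid cells were higher in the USP6 library, whereas genes of granule proteins were lower more often than higher. Of 19 expressed maturation markers, 12 were higher and 1 lower, with a median of 0.79 at percentiles 99.8 and 99.0. The integrin gene ITGAM had 0.114 and 3.20 FPKM, 28.0-fold higher (15.0 to 59.1), the Fc receptor chain FCER1G 0.431 and 6.57 FPKM, and LILRB2, which overlaps RPS9, 6 and 333 counts. Of the 12 higher members, 7 lay under 1 FPKM in the pccl library, and 22 further markers in the table reached 1 FPKM in neither library, 11 of them with a log2 ratio below 0 and 3 above. Over all 33 markers with a count the median was 0.17 at percentile 97.7, and with a filter of 5 FPKM, which leaves fewer members, it was 0.77 at percentile 91.6. Of 10 expressed genes of granule proteins, 5 were lower and 3 higher, with a median of -0.56 at percentiles 2.21 and 0.13. This list stayed at the low end under 5 of 11 alternatives, and its median was -0.35 both with a filter of 5 FPKM, at percentile 18.3, and without the member of largest ratio, at percentile 10.9. The genes of the serine protease family PRTN3, CTSG and AZU1 were 6.96-fold (6.13 to 7.94), 3.48-fold (3.18 to 3.81) and 2.87-fold lower (2.55 to 3.24). The myeloperoxidase gene MPO went the other way, with 27.4 and 122 FPKM (4.44-fold higher, 4.21 to 4.69). Stem and progenitor markers were split, with 5 higher and 5 lower of 13 and a median of -0.08 at percentiles 31.9 and 34.4, which was 0.21 at percentile 72.9 with 1 FPKM asked of the mean of both libraries.

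**Figure D3:**
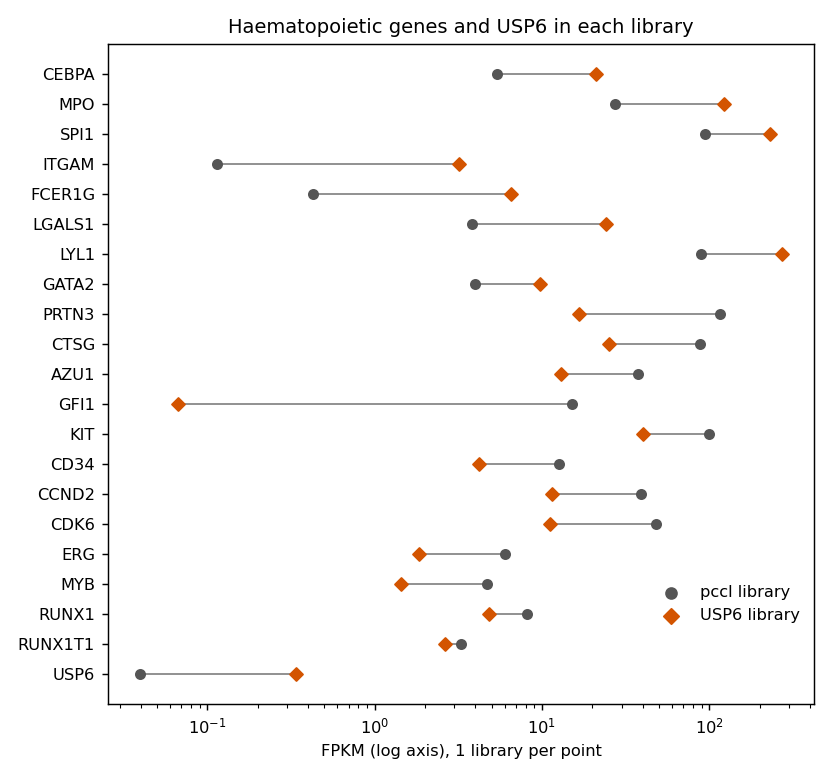
FPKM of 20 haematopoietic genes and USP6 on a log axis, with the pccl library as grey circles and the USP6 library as orange diamonds, 1 library per point. CEBPA, MPO and ITGAM lie higher in the USP6 library, PRTN3, GFI1, KIT and CD34 lower, and USP6 stays below 1 FPKM in both.

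Markers of other cell types were mostly unexpressed, and lists with under 5 expressed members have no percentile. In the T and natural killer cell list, 4 of 21 genes were expressed and 3 were higher, with a median of 1.24. CD3E had 0.890 and 4.34 FPKM and CD2 0.156 and 3.10 FPKM, whereas CD3D, the most abundant, had 27.8 and 22.6 FPKM. In the B cell list, 3 of 4 expressed genes were higher, with a median of 1.38, among them CD79A with 2.60 and 10.5 FPKM. The erythroid list had 2 expressed genes, EPOR higher and the transferrin receptor gene TFRC 7.12-fold lower (6.52 to 7.78), with a median of -0.82. The megakaryocyte list had GP1BB and ITGA2B, both higher with a median of 0.75 that became -0.03 after GC centring. The mast cell and basophil list had GATA2 higher and CTSG lower, with a median of -0.33, and in the stromal and epithelial list EPCAM alone was expressed, with 17.3 and 8.77 FPKM. USP32 was the expressed member of the list of USP6 and its relatives. Over all members with a count, the B cell, megakaryocyte and mast cell lists lay at percentiles 98.9, 98.6 and 98.3, with medians of 0.22, 0.11 and 0.17. The erythroid median was then 0.04 at percentile 67.5, that of T and natural killer cells 0.13 at 89.1 and that of stromal and epithelial genes -0.03 at 15.6.

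Interferon-stimulated genes were more often higher than lower, and other immune and signalling lists went both ways. Of 27 interferon-stimulated genes, 10 were higher and 5 lower, with a median of 0.31 at percentiles 84.1 and 92.9. After GC centring it was 0.41 at percentile 98.5. With a filter of 5 FPKM it was 0.24 at percentile 62.0, and over all members with a count 0.15 at percentile 91.4. Of the 10 higher members, 8 lay under 1 FPKM in the pccl library, and 4 of the 5 lower did so in the USP6 library. ISG15 was 4.2-fold (3.29 to 5.40), GBP2 7.80-fold (5.73 to 10.8) and OASL 6.08-fold higher (4.47 to 8.43), and BST2 was 6.68-fold lower (3.0 to 17.5). Antigen presentation genes were split, 5 higher and 5 lower of 12, with a median of 0.19 at percentiles 62.9 and 52.9, and of -0.02 at percentile 24.6 over all members with a count. HLA-E, whose reads may be shared with related genes, was 2.33-fold higher (2.22 to 2.45), and the peptide-loading gene TAPBP was 16.6-fold lower (13.7 to 20.3). NF-kappaB targets had 7 higher and 3 lower of 15 and a median of 0.38 at percentiles 75.9 and 71.0, with CXCL8 10.5-fold lower (7.38 to 15.3) and ICAM1 2.90-fold higher (2.25 to 3.77). JAK-STAT genes had 6 lower and 2 higher of 13, with a median of -0.50 at percentiles 3.95 and 0.67, and of -0.16 at percentile 33.9 with a filter of 5 FPKM. STAT5A was 6.37-fold (4.65 to 8.89) and STAT3 2.61-fold lower (2.26 to 3.03), and TYK2 was 3.03-fold higher (2.81 to 3.27). Wnt receptors and targets had 3 lower and 2 higher of 12 (median -0.32, percentiles 11.8 and 9.85), with FZD6 14.9-fold lower. TGF-beta targets had 2 higher and 1 lower of 10 (median 0.18, percentiles 68.9 and 36.8), ID2 being 7.15-fold higher (5.69 to 9.08) and the receptor gene TGFBR2 6.85-fold lower (5.26 to 9.05). Immediate early genes had 7 lower and 4 higher of 18 (median -0.26, percentiles 12.3 and 1.31), with KLF2 5.69-fold and JUN 2.06-fold lower. The median of this list was 0.21 at percentile 53.8 with a filter of 5 FPKM and -0.45 at percentile 1.87 after GC centring.

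Heat shock genes were lower together. Of 19 expressed members, 11 were lower and 0 higher by at least 1.5-fold, and the median of -0.74 lay at percentiles 0.12 and 0.08. The chaperone gene HSP90AB1 had 157 FPKM in the pccl library and 71.2 in the USP6 library (2.21-fold lower, 2.12 to 2.30), HSPA8 was 3.63-fold lower (3.27 to 4.04) and its partner DNAJA1 3.54-fold lower (3.22 to 3.88). Genes of the unfolded protein response and the ATF4 pathway had 12 lower and 5 higher of 28, with a median of -0.25 at percentiles 6.23 and 5.01. After GC centring the median was -0.37 at percentile 2.19, and with a filter of 5 FPKM it was -0.09 at percentile 23.3. Within this list, the endoplasmic reticulum chaperone gene HSPA5 was 3.39-fold lower (3.07 to 3.74) and EDEM1 8.08-fold lower (6.92 to 9.49), while the transcription factor genes ATF4 and DDIT3 were 2.68-fold (2.63 to 2.73) and 2.53-fold higher (2.17 to 2.97). p53 targets were split, with 3 higher and 3 lower of 14 (median 0.03, percentiles 52.6 and 39.9), and BAX was 3.62-fold lower (2.84 to 4.65). Genes of apoptosis had 5 lower and 2 higher of 19 (median -0.28, percentiles 13.6 and 12.4), and with a filter of 5 FPKM the median was 0.09 at percentile 56.8.

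Genes of sterol and fatty acid synthesis were lower in the USP6 library. Of 25 expressed members, 13 were lower and 2 higher, with a median of -0.66 at percentiles 0.27 and 0.01. Besides HMGCS1, the desaturase gene SCD had 75.7 and 16.5 FPKM (4.59-fold lower, 4.30 to 4.90) and IDI1 was 5.59-fold lower (4.44 to 7.11). EBP was an exception, 3.58-fold higher (3.22 to 3.99). Genes of iron handling and haem synthesis had 8 lower and 2 higher of 17, with a median of -0.47 at percentiles 2.30 and 1.77, of -0.45 at percentile 2.83 without the member of largest ratio and of -0.19 at 7.41 over all members with a count. TFRC led them, and the ferritin gene FTH1, whose counts are uncertain because of expressed pseudogenes, was 2.75-fold lower. Genes of glycolysis and hypoxia had 9 lower and 4 higher of 22, with a median of -0.39 at percentiles 3.66 and 1.81. It was -0.59 at percentile 1.83 with a filter of 5 FPKM and -0.45 at 1.93 with 1 FPKM asked of the mean. Over all members with a count it was -0.12 at 4.38, without the member of largest ratio -0.37 at 5.13 and with a pseudocount of 5 -0.20 at 3.67. LDHA was 9.56-fold (8.56 to 10.7), PGAM1 4.88-fold and PGK1 4.05-fold lower (3.67 to 4.48), whereas GAPDH had 212 and 485 FPKM and PFKL was 3.95-fold higher (3.58 to 4.38). Nuclear genes of the respiratory chain had 15 lower and 3 higher of 41, with a median of -0.31 at percentiles 2.06 and 5.03, and of -0.11 at percentile 28.4 after GC centring. This list stayed at the low end under 5 of 11 alternatives, and left it with a filter of 5 FPKM (percentile 3.15) and with the trimmed mean (2.91) too. SDHB was 3.38-fold lower (2.79 to 4.12). The 13 mitochondrially encoded messages had a median of 0.09 at percentiles 43.2 and 85.1, with 2 lower, MT-ATP6 and MT-ND4L. Autophagy and lysosome genes had 4 lower and 1 higher of 21 (median -0.09, percentiles 31.2 and 27.7), LAMP1 being 24.3-fold lower (17.2 to 35.3). With a filter of 5 FPKM, which leaves fewer members, the median of this list was -0.91 at percentile 2.75.

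Genes of growth and ribosome assembly counted as MYC targets were lower more often than higher. Of 37 expressed genes on this list, which holds MYC too, 16 were lower and 4 higher, with a median of -0.38 at percentiles 0.93 and 0.59, and the same median at percentile 2.67 with a filter of 5 FPKM. The ornithine decarboxylase gene ODC1 had 67.9 and 14.5 FPKM (4.69-fold lower, 4.31 to 5.10) and DKC1 was 4.49-fold lower (3.83 to 5.27). MYC itself had 0.199 and 1.43 FPKM. DNA replication genes went both ways, with 12 lower and 5 higher of 37 (median -0.08, percentiles 24.5 and 40.7). MCM4 was 8.47-fold (7.43 to 9.70) and TYMS 6.66-fold lower (5.33 to 8.41), and CDT1 was 4.31-fold (3.97 to 4.67) and MCM5 2.43-fold higher (2.30 to 2.57). Mitotic genes had 13 lower and 4 higher of 36 (median -0.31, percentiles 3.22 and 27.2), with CCNA2 2.97-fold lower (2.51 to 3.52) and MKI67 2.54-fold higher (2.38 to 2.71). With a filter of 5 FPKM the median of the mitotic list was 0.06 at percentile 49.3, and over all members with a count it was -0.34 at percentile 1.29. Among 15 regulators of the G1 phase, 2 were lower and 2 higher (median -0.15, percentiles 24.97 and 26.1). The kinase gene CDK6 had 48.1 and 11.2 FPKM, 4.32-fold lower (4.10 to 4.54). Ribosomal protein genes had 17 higher and 7 lower of 52 (median 0.31, percentiles 89.7 and 97.8). RPL4 was 2.56-fold higher (2.52 to 2.59) and RPL30 3.08-fold lower (2.91 to 3.26), though many of these genes have expressed pseudogenes.

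Replication-dependent histone genes were higher among the few that were expressed, at low counts apart from H1-2. Of 11 in the table, 5 were expressed and 4 of these higher, with a median of 1.21 at percentiles 99.5 and 98.7. H2BC5 and H4C8 reached 1 FPKM in the USP6 library alone, and over all 11 the median was 0.36 at percentile 96.8. H2BC5 and H4C8 each had 2 and 59 counts. Messages of replication-dependent histone genes largely lack a poly(A) tail. Whether this holds for the transcripts counted here is not known. The loci listed for H2BC5 (26158146 to 26171349) and H4C8 (26277609 to 26285638) are longer than that of H1-2. RN7SL2 and RN7SL1, the RNAs of the signal recognition particle, were 5.24-fold (3.53 to 8.02) and 4.42-fold higher (2.87 to 7.05), and the ribonuclease P RNA RPPH1 had 2 and 17 counts. In the list of nuclear and small RNA host transcripts that holds them, 6 of 18 were higher and 3 lower (median 0.10, percentiles 46.8 and 59.7), the long RNA TUG1 being 7.62-fold lower (6.50 to 8.98).

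Genes of the ubiquitin system were lower more often than higher. Of 31 proteasome subunits, 13 were lower and 0 higher, with a median of -0.39 at percentiles 1.63 and 7.49, so the list was not at the low end with GC matching. Its median was -0.29 at percentile 8.98 with a filter of 5 FPKM, -0.34 at 2.55 without the member of largest ratio and -0.33 at 3.62 after GC centring. PSMD11 was 5.47-fold lower (4.73 to 6.35). Of 41 deubiquitinase genes other than USP6, 13 were lower and 5 higher, with a median of -0.35 at percentiles 1.32 and 7.47, and of -0.44 at percentile 16.7 with a filter of 5 FPKM, which leaves fewer members, and of -0.29 at 3.5 with 1 FPKM asked of the mean. USP10 was 7.41-fold lower (5.55 to 10.1), USP14 2.96-fold lower (2.61 to 3.35) and USP7 3.51-fold higher (3.07 to 4.03). A list of ubiquitin ligases reported to act on RUNX1 and of other genes had 6 lower and 3 higher of 13 (median -0.22, percentiles 18.2 and 13.99). The ligase gene SIAH2 was 2.59-fold lower (2.16 to 3.12), and UBA7, one of the other genes, was 8.61-fold higher (5.99 to 12.7). Corepressors and chromatin enzymes had 2 lower and 0 higher of 15 (median 0.02, percentiles 45.5 and 46.9), SUZ12 being 8.55-fold lower (7.10 to 10.4). Adhesion and migration genes had 7 higher and 2 lower of 14 (median 0.41, percentiles 90.0 and 80.6), with ITGA4 3.51-fold lower (2.92 to 4.23). The median of this list was 0.23 over all members with a count, at percentile 97.6. It was also 0.23 with a filter of 5 FPKM, at percentile 66.1, and without the member of largest ratio, at percentile 73.2.

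Besides those given above, several named genes overlap another expressed gene, and their counts are uncertain because the strandedness is not known. Among them are RUNX1 with the pseudogene EZH2P1, USP32 with C17orf64, GATA2 with GATA2-AS1, CDK6 with CDK6-AS1, DDIT3 with MARS1, TYMS with ENOSF1, CCNA2 with EXOSC9, USP14 with THOC1, RPL4 with ZWILCH, GAPDH with AC006064.4, MT-ND4L with MT-ND4, MT-ATP6 with MT-ATP8 and MT-CO3, and RN7SL1 with RPS29. GAPDH, PGAM1, ATF4, SUZ12, MKI67 and MT-ND4L have expressed pseudogenes, which also makes their counts uncertain.

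In all, 10 of the 35 lists with a percentile lay below percentile 2.5 and 2 above percentile 97.5 with expression matching. Lists of genes drawn at random would put 1.75 beyond either end. The lists share members and genes of a list may vary together, so that number is not what differences between cultures alone would give. With GC matching as well, 10 lay below and 3 above, 7 and 2 of them at the same end under both. Of the 12 lists at an end with expression matching, the heat shock and sterol synthesis lists stayed there under all 11 alternatives run. Other scalings shifted the USP6 library against the pccl library by up to 0.17 on the log2 scale, before the pseudocount. With a filter of 5 FPKM the medians of the mitotic, immediate early, apoptosis and nuclear RNA lists had the opposite sign.

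**Figure D4:**
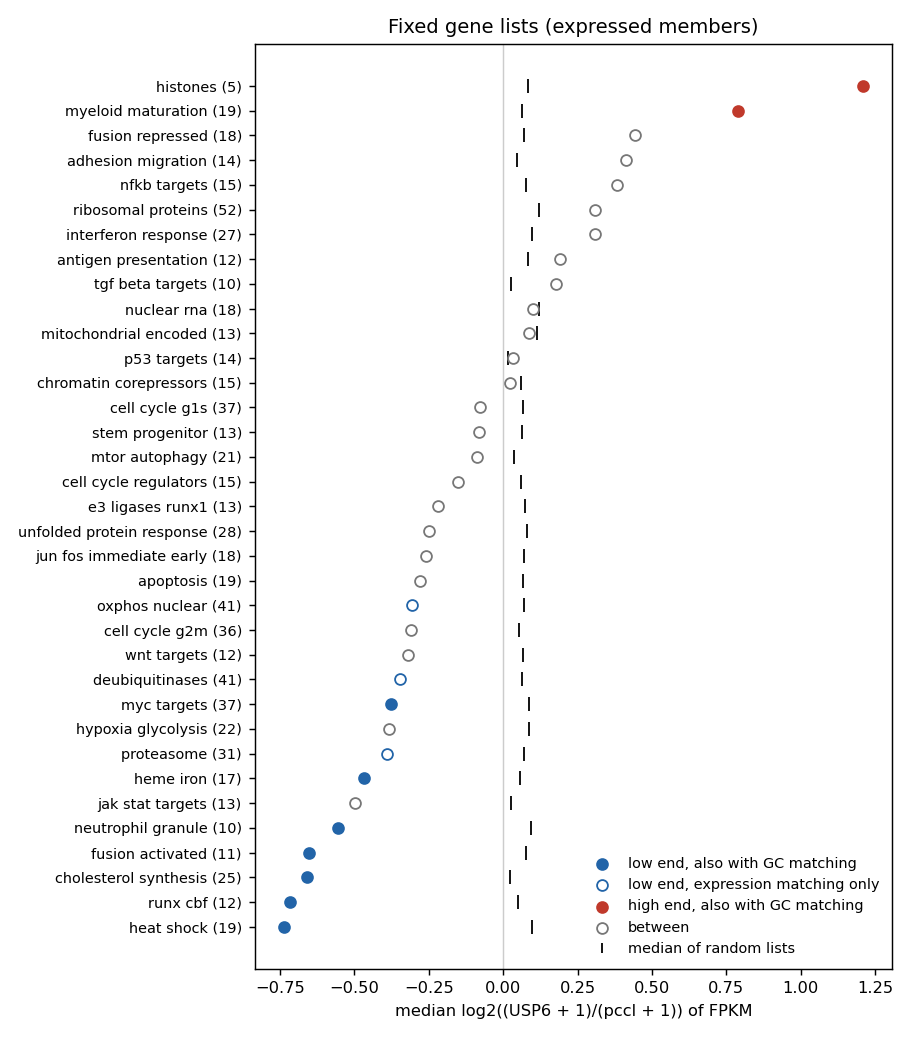
Median log2((USP6 + 1)/(pccl + 1)) over the expressed members of each of the 35 lists with a percentile (x axis), with the number of members in brackets and a vertical tick at the median of expression-matched random lists. Filled blue and red points lie below percentile 2.5 or above percentile 97.5 under both kinds of matching, open blue points with expression matching alone, and among these 35 lists heat shock is lowest at -0.74 and histones highest at 1.21.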

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

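Centring on GC, GC-matched lists, depth from nuclear genes alone and lists with 1 FPKM asked of the mean or with all members that have a count were chosen after the data were seen, and the percentile limits after the list medians. The other alternatives were fixed before. No paired analysis was possible because each group held 1 library and no test was run. The number of genes higher and lower, 1396 and 1156, depended on the pseudocount, with 2295 and 1993 at 0.1 and 364 and 301 at 5. It was 808 and 682 with a filter of 5 FPKM, which leaves fewer genes, and 2831 and 2489 at the 1.5-fold limit. Scaled to the same, larger FPKM sum, 2199 of 11529 expressed genes were higher. The higher made up 65.2% of the counted genes, against 54.7% as deposited. That share was 46.9% with the trimmed mean, 48.6% with a median of 0 and 45.8% with nuclear depth, so which direction had more genes depended on the scaling. No other setting moved either count by over 1.5 times, and leaving out the filter moves nothing, since a pseudocount of 1 already excludes genes under 1 FPKM. Before the pseudocount, scaling shifted the USP6 library against the pccl library on the log2 scale by 0.17 for the same FPKM sum, -0.10 for the trimmed mean and -0.12 for nuclear depth. With the pseudocount, the log2 ratios of low genes shifted by other amounts. With the filter of 5 FPKM, list medians turned from -0.31 to 0.06 for mitotic, -0.26 to 0.21 for immediate early and -0.28 to 0.09 for apoptosis genes, and from 0.10 to -0.11 for nuclear RNAs. Those of the p53, mitochondrially encoded and corepressor lists, all within 0.17 of 0, turned sign with the trimmed mean. With 1 FPKM asked of the mean, the stem cell list turned from -0.08 to 0.21 and the corepressor list from 0.02 to -0.05. Over all members with a count, antigen presentation turned from 0.19 to -0.02. Among lists with under 5 expressed members, the erythroid list then turned from -0.82 to 0.04, the mast cell list from -0.33 to 0.17 and USP6 with its relatives from -0.81 to 0.09. The USP6 ratio of 8.60 became 0.668 when summed with USP32 and the TBC1D3 family, because USP32 has most of the summed counts. Lists at the low end numbered 6 instead of 10 with a pseudocount of 5, 5 with the filter of 5 FPKM (30 lists left) and 6 without the member of largest ratio. At the high end, the maturation list left with that filter, and the histone list had no value with that filter or without that member, as under 5 members were left. That was so, too, with 1 FPKM asked of the mean, which left 1 list at the high end. Over all members with a count 5 of 42 lists lay at the high end, of which the maturation list alone is among the 2, as the histone list was at percentile 96.8. Causes other than those given were not tested. Of 225 named genes, a pseudocount of 5 took 104, GC centring 51 and the trimmed mean 12 to under a log2 ratio of 1 in size, and no gene or list at a limit changed direction in any setting run. Depth limits the low genes, such as USP6 with 8 and 70 counts.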

Other observations

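All tests of the complexes and of MT-ATP6 were chosen after the result was seen, and those of GC content before, although the trend over protein-coding genes was known by then.

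Gene classes differed in their direction. Of 995 expressed long non-coding RNA genes, 285 were higher and 54 lower in the USP6 library, with a median log2 ratio of 0.58, or 0.54 after GC centring. Their share of all counts was 0.827% in the pccl library and 1.05% in the USP6 library. Of 574 expressed processed pseudogenes, 82 were higher and 140 lower, with a median of -0.24, whereas their share of all counts was 2.51% in the pccl library and 2.91% in the USP6 library. Among abundant genes, 37 had at least 500 counts in the pccl library and at most 5% of that number in the USP6 library, HGF, GFI1 and ZNF146 among them, and 9 had the opposite pattern. The mitochondrial ribosomal RNA MT-RNR1 had 20104 and 72517 counts, 3.55-fold higher, and MT-RNR2 384782 and 502312.

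GC-rich genes were higher in the USP6 library, with rho 0.46 over protein-coding genes. Gene length is argued against as the cause, since the median rho inside 10 classes of transcript length was 0.43. A different GC bias of the libraries would act on every class of RNA. The Spearman coefficient was 0.22 over long non-coding RNAs (0.16 to 0.28) and 0.117 over processed pseudogenes (0.042 to 0.201), both above the limit of 0.1 set beforehand for such a bias, although the latter interval spans it. GC bias may thus account for part of the trend, and an effect of USP6 stays open and untested, since each group is 1 library.

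Subunits of the proteasome, and those of the ribosome, had log2 ratios that differed from each other. Their SDs were below that of protein-coding genes in general, 0.87 over 8260 expressed genes. Those genes were not matched to the subunits on expression, so the comparison does not show that subunits vary together. The SD over genes was 0.51 in the proteasome, from -1.91 for PSMD11 to 0.30 for PSMC1, and 0.71 over the ribosomal proteins. The GC trend is argued against as the cause, since the SD after centring was 1.03 and 1.07 times that before. Over the nuclear respiratory chain genes, which belong to several complexes, the SD was 0.65 and centring left 0.961 of it. Ordinary differences between single libraries, uneven copying of molecules before sequencing and regulation gene by gene could each give such a spread, and none was tested.

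MT-ATP6 had 594565 counts in the pccl library and 75784 in the USP6 library, 7.98-fold lower, while the log2 ratios of the other 12 mitochondrial messages lay between -0.76 and 0.51. Reads assigned to nuclear copies are argued against, since the difference in counts of the 23 listed MT-ATP6 pseudogenes was -1.07% of the counts that MT-ATP6 lacked in the USP6 library. A lower level of the message it shares with MT-ATP8 is also argued against, as the log2 ratio of MT-ATP8 was 2.58 above that of MT-ATP6. Assignment of the missing reads to its neighbours, with which it shares 46 bases (MT-ATP8) and 1 base (MT-CO3), is argued against as the whole cause, since without those reads both together would have a log2 ratio of -1.70, below the -0.76 of the lowest of the 10 remaining messages by more than their SD of 0.42. Reads left uncounted, or a difference within the message, may remain and were not tested.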
